A study of Homo sapiens with 6 samples.

How the data were processed

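RNA sequencing libraries from A549, H1299 and a line labelled H2030, each with an empty vector or a malin (NHLRC1) vector, were analysed from gene-level tables. Per the labels, the cells were lung cancer lines at passage 5, RNA was extracted with a column kit, and libraries followed Illumina protocols. The values were FPKM (fragment numbers scaled to transcript length and to the library total), deposited by the authors and named so per the file headers. The submitters' processing notes name cutadapt, FastQC, STAR and Cufflinks and the build hg38, with no versions. Whether counting used strand is not given in the sources used here. FPKM depends on the total of a library, so a few abundant genes can shift all others, and genes that overlap or have near-identical copies can trade fragments between libraries.

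Each table held 19903 genes by Entrez identifier. Symbols that were blank or had been turned into dates (37) were replaced by Entrez identifier where possible (35). Gene types came from the RefSeq table of GRCh38.p14, which matched 19770 genes, 17537 of them protein coding, and left 133 unmatched. The tables carry no coordinates, and positions are from GENCODE release 29 on GRCh38, the same assembly as hg38.

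No counts were used here. Low FPKM values of genes with 1 transcript of 600 to 2000 bases, multiplied by the transcript length less 100 bases, clustered at whole multiples of 1 fragment. Between 75.2% and 78.7% of low values lay within 0.2 of a whole number, where 40% would by chance for a step fixed in advance. The step and the 100 bases were chosen from these same values, so the chance share can exceed 40%. The step gave 8400000 to 10800000 fragments per library and the fragment numbers behind NHLRC1. Binomial intervals on those numbers cover counting error only.

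Groups followed the vector in the labels, and pairs followed the cell line label. There was 1 library per line and vector, so replication exists only across lines, and no label says whether cultures were independent. Log2(FPKM+1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend) with cell line as a block, on 12182 protein-coding genes with a mean FPKM of at least 1, with Benjamini-Hochberg adjustment at 0.05. The fit had 2 residual degrees of freedom and a median prior of 3.9. On simulated data for this comparison (12182 genes, 200 changed equally in all lines, with the real fold changes of each line shuffled over genes as noise), 0%, 82% and 99.5% of changed genes were recovered at log2 changes of 0.5, 1 and 2, with 0 false calls. The simulation assumes the same change in each line and 200 changed genes. The adjusted p of a gene depends on how many genes change, so the simulation does not give the recovery where few do. Of 34 gene lists fixed before the data were examined, 32 had at least 5 measured genes and were tested with camera (preset correlation 0.01, and an estimated correlation) and fry. In a simulated list comparison over 12182 genes, a list of 24 genes shifted by 0.3 was recovered and 0 other lists were called. Its noise was also shuffled over genes, which removes co-regulation. It therefore cannot show how often lists of co-regulated genes are called falsely with the preset correlation.

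Within a line no test was possible. Log2 ratios were counted at 2-fold and 1.5-fold, and list medians were set against 10000 random lists of the same size matched on mean expression in 20 bins, without accounting for co-regulation. Exact paired permutation tests used sign flips over the 3 lines. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

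Named genes were NHLRC1 and EPM2A; up to 10 genes per direction past the adjusted threshold, filled, where fewer passed, with genes of the same direction in all 3 lines ranked by their smallest absolute log2 difference; the 5 highest and 5 lowest of each line; and up to 4 members of each list described, by absolute mean log2 difference. Genes of cell identity outside the lists were chosen after their values were seen. Values of some genes that these rules select are not reported here. Alternatives were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, no block, leaving out each line, all gene classes, and no intensity trend. The comparison of A549 with H1299 alone was added after the data were seen.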

Results

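Messenger RNA was measured by RNA sequencing in 3 human cell lines labelled as lung cancer lines. Each carried either an empty vector or a vector for malin, the protein encoded by NHLRC1. A549 and H1299 are widely used lines derived from human non-small-cell lung tumours, and the third pair of libraries was labelled H2030, another lung adenocarcinoma line. Malin is an E3 ubiquitin ligase that acts with the glycogen phosphatase laforin, the product of EPM2A. The 6 libraries comprised 1 empty-vector and 1 malin library per line, so each group held 3 libraries and no line had a replicate of either vector. The deposited unit was FPKM, and each library listed 19903 genes. Depth was estimated from the spacing of low values at 10400000 and 10500000 fragments for the A549 libraries with empty and malin vector, 10800000 and 9900000 for H1299, and 8400000 and 9800000 for the libraries labelled H2030. Between 11861 and 13179 genes per library reached at least 1 FPKM.

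NHLRC1 was higher in the malin library of each line. In A549 it stood at 1.21 FPKM with the empty vector and 6.82 FPKM with malin, a ratio of 5.64 (95% exact binomial interval 3.74 to 8.85, counting error only). In H1299 the values were 2.85 and 119.2 FPKM, a ratio of 41.8 (interval 32.7 to 54.1). In the pair labelled H2030 they were 0.18 and 3.69 FPKM, a ratio of 20.5 (interval 7.35 to 110.4) that rests on an estimated 3 fragments in the empty-vector library. The H1299 malin library thus held an estimated 2523 NHLRC1 fragments, against 154 in A549 and 78 in the library labelled H2030. On the log2(FPKM+1) scale, which understates changes of low genes, the mean over lines was 2.93 ± 1.77 (SD, n = 3). An exact paired permutation test gave a two-sided p of 0.25, the smallest that 3 pairs allow. EPM2A was lower in the malin library of each line, at 1.14 against 0.98 FPKM in A549, 4.24 against 3.96 in H1299 and 2.96 against 1.56 in the pair labelled H2030. Its mean log2 difference was -0.27 ± 0.31 (SD, n = 3; exact paired permutation p = 0.25), and -0.10 without the libraries labelled H2030.

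**Figure D1:**
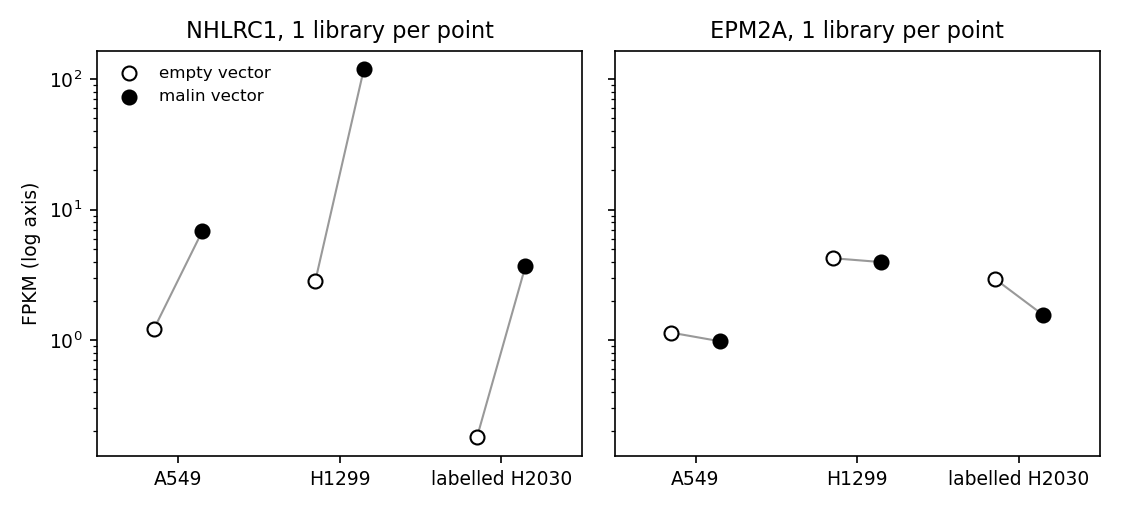
FPKM of NHLRC1 (left) and EPM2A (right) on a log axis, 1 point per library, with open points for the empty vector and filled points for malin, joined within a line. NHLRC1 was higher with malin in all 3 pairs and reached 119.2 FPKM in H1299, while EPM2A lay between 0.98 and 4.24 FPKM in the 6 libraries.

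NHLRC1 (Entrez gene 378884) lies on chromosome 6 of build hg38, from 18120440 to 18122687 on the minus strand, as a gene of 1 exon in GENCODE release 29. Its coding sequence spans 18121422 to 18122606, with untranslated regions from 18120440 to 18121421 and from 18122607 to 18122687. EPM2A (Entrez gene 7957) lies on the same chromosome from 145382535 to 145736023, also on the minus strand. The FPKM values are per gene, so reads from an inserted coding sequence and from the resident gene were not told apart.

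The pair labelled H2030 stood apart in genes that mark cell identity. TM4SF1, a tetraspanin-like surface protein, was at 0.23 and 0.19 FPKM in its empty-vector and malin libraries, against 136.3 and 160 in A549 and 292.3 and 297 in H1299. ITGA3, an integrin subunit, was at 3.56 and 3.27 FPKM, against 120.8 to 145.2 in the A549 and H1299 libraries. The neurofilament gene NEFM was at 30.5 and 52.6 FPKM in that pair and at most 2.11 in the other 4 libraries, and NEFL was at 23.4 and 31.7 FPKM. These were 2 of 4 neurofilament genes examined. INA, at 9.3 and 6.12 FPKM, lay below both other lines. NEFH, at 0.44 and 0.26 FPKM, lay below its 7.2 and 8.77 FPKM in H1299. Of 21 carcinoma surface and calcium-binding genes, 15 had a mean in that pair below both other lines. The FPKM column of its empty-vector library was headed H2030. That of its malin library was headed with the short name of HEK293T, a human embryonic kidney line, whereas the labels of that library name H2030. The pair is therefore called the libraries labelled H2030 throughout. Across genes, which are not independent replicates, Pearson's r of log2(FPKM+1) between the 2 vectors was 0.996 in A549, 0.997 in H1299 and 0.975 in the pair labelled H2030, and 0.758 to 0.818 between lines.

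**Figure D2:**
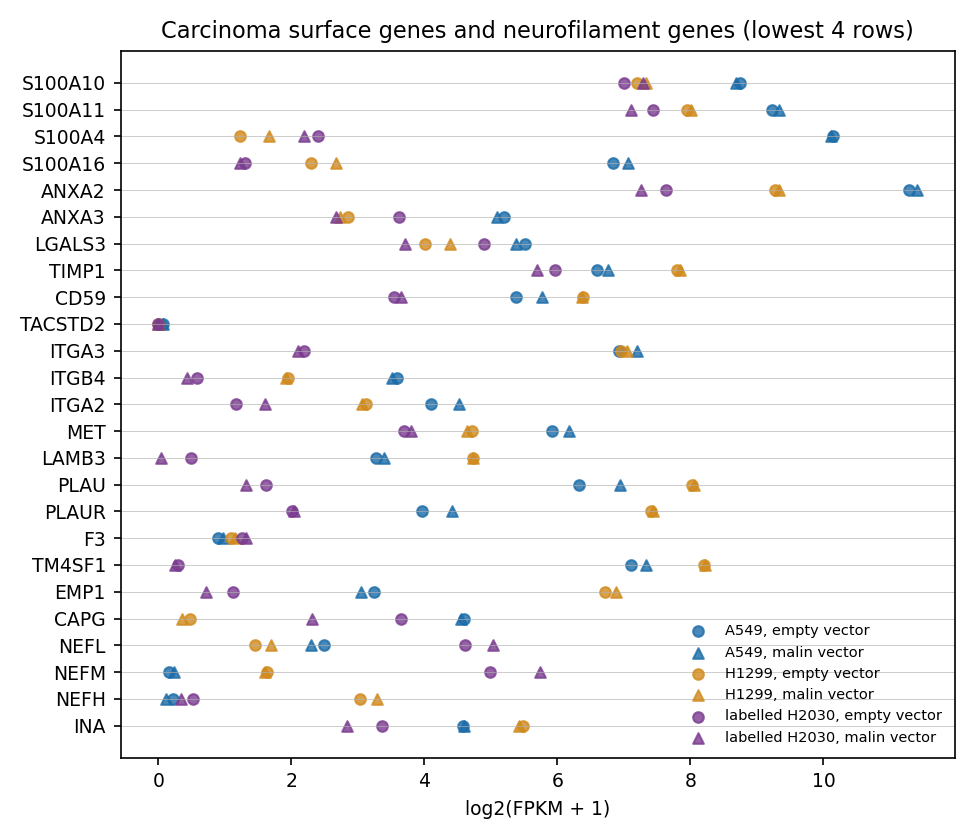
Level of 21 carcinoma surface and calcium-binding genes and 4 neurofilament genes as log2(FPKM+1), with circles for empty-vector and triangles for malin libraries and 1 colour per line. In the libraries labelled H2030, TM4SF1, ITGA3 and PLAU lay far below both other lines, and NEFL and NEFM lay above them, while NEFH and INA did not.

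Among markers of other cell types, CD68, a macrophage marker, was at 45.7 and 53.2 FPKM in the H1299 libraries with empty vector and malin, and PDPN, the podoplanin gene, was at 23.5 and 21.4 FPKM in the libraries labelled H2030. Of the immune cell markers, 3 genes reached the expression filter, and the list was too short to test. The fibroblast and endothelial markers held 5 measured genes, PDPN among them, with a median log2 difference of 0 in each line and an adjusted p of 0.684 by limma's camera test. Among lung lineage genes, NKX2-1, a transcription factor of lung epithelium, was listed at 0 in both A549 libraries and stood at 1.85 and 3.78 FPKM in the libraries labelled H2030. The 10 measured lung lineage genes had median log2 differences of -0.0042, 0.05 and 0.06 in A549, H1299 and the pair labelled H2030. The 17 measured epithelial identity genes had medians of 0.02, 0.0045 and -0.19. CDH1, the epithelial cadherin, was at 3.27 and 1.67 FPKM in A549.

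Which genes differed between malin and empty vector across the 3 lines was tested with the line as a block. NHLRC1 had the largest mean difference, 2.93 ± 0.60 (limma's moderated SE, n = 3 pairs) on the log2 scale, and did not pass (limma, adjusted p = 0.927). That SE draws on the variance of other genes, and the SD of NHLRC1 over the 3 lines was 1.77. Of 12182 protein-coding genes, 0 passed an adjusted p of 0.05 in limma. An unadjusted p under 0.05 was reached by 213 (1.75%), fewer than the share of 0.05 expected with no differences. Of these genes 1345 were higher in all 3 lines, where 1428 were expected if the lines were independent, and 1380 were lower, where 1476 were expected. Genes with the same direction in all 3 lines are given by value only. Higher in each malin library were NPB, a neuropeptide precursor, by at least 0.34 on the log2 scale, NID2, a basement membrane protein, by at least 0.29, and TTC32 by at least 0.28. NRG2, ERVMER34-1, ZNF695, C1orf63, TCEAL1 and TESK2 followed, each higher by at least 0.25 in every line. Lower in each malin library were AGAP9, with log2 differences of -0.38, -0.36 and -0.39, and SYCE1L, with -0.56, -0.49 and -0.36, in A549, H1299 and the pair labelled H2030. IRF7, a transcription factor of the interferon response, had differences of -0.30, -0.31 and -0.65 in the same order. DNASE1, FNDC8, PLCD4, GGT7, TAF1D, FAM82A1 and AGA were also lower in each line. Several of these genes had low levels. NPB was at 0.18 and 1.24 FPKM in A549, and SYCE1L at 0.62 and 0.26 FPKM in the pair labelled H2030. The mean log2 difference of NPB was 1.27 with a pseudocount of 0.1 and 0.20 with 5. TCEAL1 and TAF1D were higher, at 13.3 FPKM or more in every library. Without the libraries labelled H2030, 1 gene passed, SULT1A3, which was lower (limma, adjusted p = 0.0178). In that fit 491 genes (4.03%) had an unadjusted p under 0.05 (limma), again fewer than the share of 0.05 expected with no differences. SULT1A3 shares nearly identical sequence with SULT1A4, and its value is uncertain.

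The medians of the amino-acid stress, cholesterol synthesis, heat shock, histone, glycolysis and S-phase lists lay farthest from 0 in the pair labelled H2030. Log2 differences over all genes were also widest in that pair (SD 0.40, against 0.18 in A549 and 0.16 in H1299). The 6 lists were those of 32 that passed limma's camera test over the 3 lines with its preset correlation. With an estimated correlation 0 lists passed (limma camera, adjusted p = 0.812 for each of the 6, smallest unadjusted p of any list 0.184). The fry test also passed 0 lists (limma, adjusted p = 0.866 for each of the 6). The 30 genes of the ATF4 and amino-acid stress response had a mean log2 difference of -0.49, and of -0.02 without the libraries labelled H2030 (limma camera, adjusted p = 2.3e-09 with the preset and 0.812 with an estimated correlation). Their median was -1.39 in the pair labelled H2030, -0.10 in A549 (0.01st percentile of matched random lists) and -0.02 in H1299 (8.13th percentile). Of these genes 7 were lower in all 3 lines. Their level in the empty-vector library labelled H2030 was above that of the other 5 libraries. The 24 cholesterol biosynthesis genes had a mean of 0.20, and of 0.03 without that pair (camera adjusted p = 1.61e-05, and 0.812 with an estimated correlation). Their medians were 0.46 in the pair labelled H2030, 0.11 in H1299 and -0.02 in A549, and 11 members were higher in all 3 lines. The 19 heat shock genes had a mean of 0.24, and of 0.02 without that pair (camera adjusted p = 0.00053, and 0.812 with an estimated correlation). For the 24 glycolysis genes the means were 0.12 and -0.0056 (camera adjusted p = 0.00133, and 0.812 with an estimated correlation). For the 16 replication-dependent histone genes they were -0.32 and -0.0092 (camera adjusted p = 0.00059, and 0.812 with an estimated correlation). For the 30 S-phase and E2F targets, of which 9 were lower in all 3 lines, they were -0.08 and -0.04 (camera adjusted p = 0.0226, and 0.812 with an estimated correlation). The S-phase median was -0.075 in A549, -0.01 in H1299 and -0.13 in the pair labelled H2030. Against matched random lists it lay further out in A549 (0.01st percentile) than in that pair (2.41st percentile). In each of the 6 lists 0 genes passed limma over all genes tested, and 0 passed when adjusted over the list alone. Without the libraries labelled H2030 none of the 6 passed (limma camera, adjusted p 0.112 to 0.948), and the S-phase call was also lost without A549 (adjusted p = 0.103) or without H1299 (adjusted p = 0.0563), and in the fit without the block (limma camera, adjusted p = 0.211). In that fit of A549 and H1299, 4 other lists passed with the preset correlation, each with an adjusted p of 0.957 with an estimated correlation (limma camera). These were the immediate early and AP-1 genes (camera adjusted p = 0.00722; medians 0.27 in A549 and 0.03 in H1299), the mesenchymal and EMT genes (camera adjusted p = 0.0216; 0.17 and 0.02), the YAP/TAZ targets (camera adjusted p = 0.00722; 0.24 and -0.06) and the NRF2 targets (camera adjusted p = 0.0109; -0.12 and 0.01). The YAP/TAZ and NRF2 medians thus lay on opposite sides of 0 in A549 and H1299.

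Glycogen metabolism, the pathway in which malin is known to act, did not pass the list test. Its 28 measured genes had a mean log2 difference of 0.03 (limma camera, adjusted p = 0.409), with medians of 0.04 in A549, -0.01 in H1299 and 0.0031 in the pair labelled H2030. GYS1, the muscle-type glycogen synthase, was at 12.3 and 21.8 FPKM in the libraries labelled H2030, and at 7.51 and 7.53 FPKM in H1299, a difference whose sign turned with the scaling. PHKG2, a subunit of phosphorylase kinase, was at 9.02 and 17.5 FPKM in the libraries labelled H2030. PPP1R3F, a glycogen-targeting phosphatase subunit, was lower there with malin, at 3.53 against 1.32 FPKM.

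In A549, few genes differed by 2-fold between the vectors, and immediate early genes and YAP/TAZ targets were slightly higher with malin. There were 6 genes higher and 8 lower by at least 2-fold on the FPKM+1 scale, without a replicate check. Besides NHLRC1, the highest were SULT1A4, HIST1H4K, CDK3 and BOLA2. The lowest were SULT1A3, GPX2, a glutathione peroxidase (82.8 against 32.2 FPKM), MMP7, a matrix metalloproteinase (18.6 against 7.99 FPKM), INHBB, an inhibin subunit (7.53 against 2.93 FPKM), and LOC642799. SULT1A3, SULT1A4, BOLA2 and histone genes such as HIST1H4K have near-identical copies and are uncertain. Whether CDK3 shares fragments with other genes was not examined. The 19 immediate early and AP-1 genes had a median log2 difference of 0.27 and the 22 YAP/TAZ targets 0.24, both at the 100th percentile of matched random lists, with DUSP1, a MAP kinase phosphatase, at 41 and 64.8 FPKM. The 30 mesenchymal genes had a median of 0.17, with TGFBI at 369.4 and 472.1 FPKM. The 29 NRF2 targets had a median of -0.12 and the 12 pentose phosphate and NADPH genes -0.13, all 12 of the latter lower with malin, IDH1 among them at 100.4 and 83.6 FPKM. Random lists were drawn gene by gene, so co-regulated lists leave their range more readily, and 9 of 32 lists lay outside the central 95% where 1.6 would by chance.

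In H1299, which had the highest NHLRC1 level, the libraries were the closest. There were 7 genes higher and 3 lower by at least 2-fold, without a replicate check. The highest after NHLRC1 were BLOC1S5 (0.40 against 7.87 FPKM), RBM14-RBM4, PHOSPHO2-KLHL23 and TMEFF1, and the lowest were SULT1A3, C7orf55-LUC7L2, HIST1H2BH, HIST1H4H and HIST3H2A. RBM14-RBM4, PHOSPHO2-KLHL23 and C7orf55-LUC7L2 are readthrough genes that overlap their neighbours, so these values are uncertain. Values of histone genes, which have near-identical copies, are uncertain as well. Whether BLOC1S5 and TMEFF1 share fragments with other genes was not examined. The cholesterol biosynthesis genes had a median log2 difference of 0.11, at the 100th percentile, with INSIG1, a sterol-regulated inhibitor of SREBP processing, at 36 and 41.8 FPKM. The 35 autophagy and lysosome genes had a median of 0.06 at the 99.9th percentile, and the 30 MYC targets of ribosome biogenesis -0.05, with 26 of them lower. In all, 5 of 32 lists lay outside the central 95%.

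The libraries labelled H2030 differed most, with 59 genes higher and 195 lower by at least 2-fold with malin, again without a replicate check. HSPA1A and HSPA1B, which encode the inducible HSP70 chaperone and are near-identical copies, were at 108.4 and 1006 FPKM and at 87.2 and 768.9 FPKM with empty vector and malin. INSIG1 was at 16.1 and 64.5 FPKM. The lowest genes were INHBE (19.1 against 0.57 FPKM), NUPR1 (14.8 against 0.26), S100P (12.3 against 0.49), ANKRD1, a YAP target (111.5 against 11.7), and CHAC1, a glutathione-degrading enzyme induced by ATF4 (62.6 against 7.14). The 30 ATF4 genes had a median of 61.1 FPKM in the empty-vector library, against 9.14 to 25.3 in the A549 and H1299 libraries and 16.4 in the malin library. Of these genes 26 were lower with malin by at least 1.5-fold, including the transcription factors DDIT3 (47.2 against 6.74 FPKM) and ATF3 (171 against 27.8 FPKM). Of the 16 histone genes 11 were lower by at least 1.5-fold, with HIST2H4A at 13.8 against 3.16 FPKM, though histone genes have near-identical copies. Heat shock genes had a median log2 difference of 0.44 and glycolysis genes 0.33, with PKM at 357.5 and 673.2 FPKM and LDHA at 253.4 and 479.4 FPKM. Immediate early genes had a median of -0.68 and YAP/TAZ targets -0.32, opposite in sign to A549. In this pair 12 of 32 lists lay outside the central 95%.

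**Figure D3:**
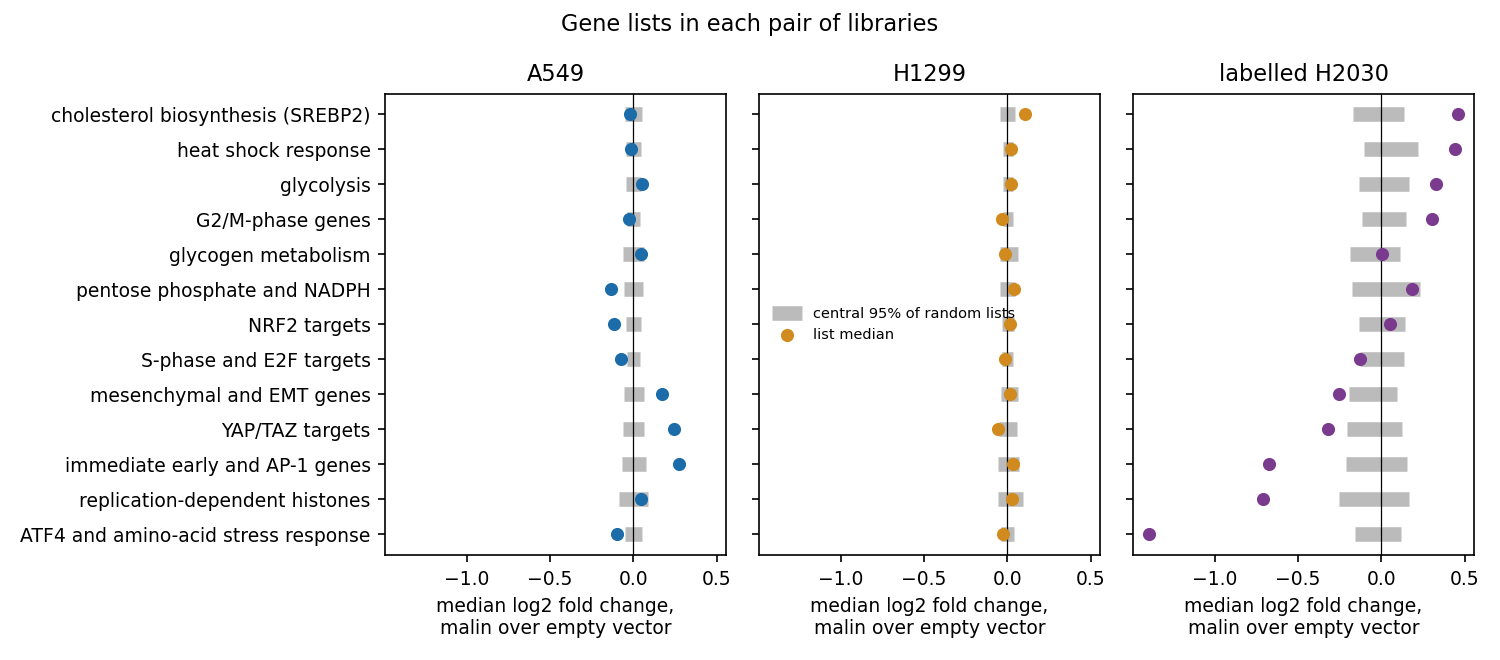
Median log2 fold change (malin over empty vector, FPKM+1 scale) of 13 gene lists in each pair of libraries (points), with grey bars for the central 95% of random lists of the same size and expression. The ATF4 list was at -1.39 in the pair labelled H2030, against -0.10 in A549 and -0.02 in H1299.

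**Figure D4:**
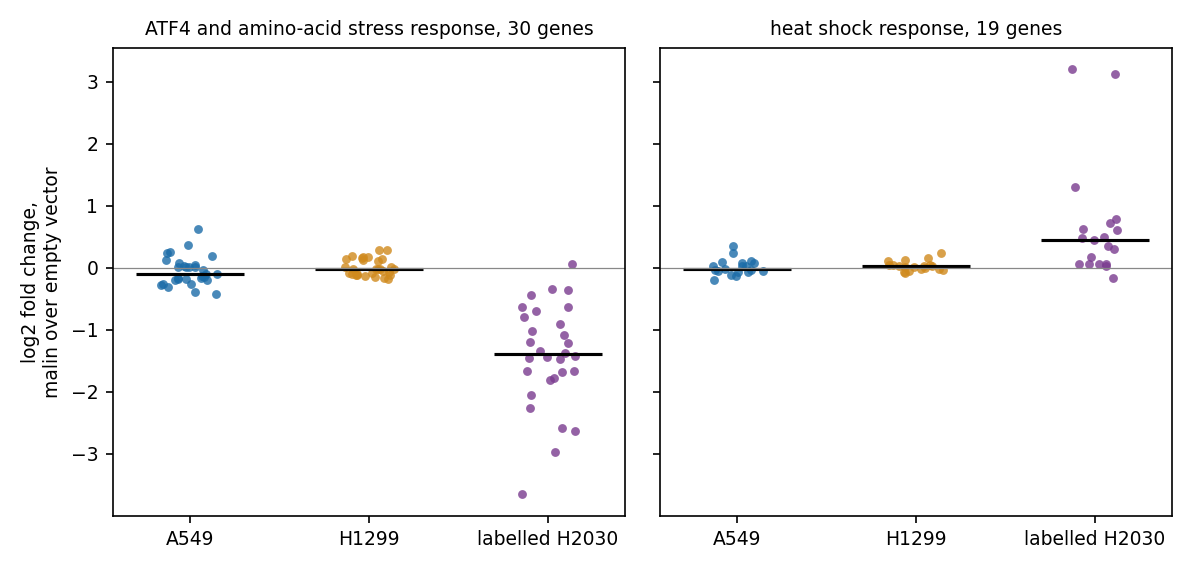
Log2 fold change (malin over empty vector, FPKM+1 scale) of each gene of the ATF4 list (30 genes) and the heat shock list (19 genes), 1 point per gene, with horizontal bars at the medians. In the pair labelled H2030, 29 of the 30 ATF4 genes were lower and 18 of the 19 heat shock genes higher.

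Whether the lines shared a response was examined from the fold changes of each line, which have separate controls. NHLRC1 was the 1 gene higher by at least 1.5-fold in all 3 lines, where 0.0093 were expected if the lines were independent, and 0 genes were lower in all 3, where 0.0074 were expected. Across the 12182 genes Pearson's r was 0.03 between A549 and H1299, 0.0013 between A549 and the pair labelled H2030 and -0.02 between H1299 and that pair. Spearman's rho was -0.04, 0.0053 and -0.04 for the same pairs. Between A549 and H1299 alone, 4 genes were higher in both by at least 1.5-fold (0.217 expected), CDK3, NHLRC1 and SULT1A4 among them, and 2 were lower (SULT1A3 and C7orf55-LUC7L2; 0.10 expected). These last counts were made after the data were seen, and SULT1A3, SULT1A4 and C7orf55-LUC7L2 share sequence with other genes. For CDK3 this was not examined.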

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

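The comparison of opposite list medians between lines was chosen after those medians had been seen. Lists are given here when their medians lay outside the central 95% of matched random lists in opposite directions in a pair of lines. The difference between lines was not tested in any of these cases, since each line had 1 library per vector.

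Immediate early and AP-1 genes had a median log2 difference of 0.27 in A549 and -0.68 in the pair labelled H2030, a gap of 0.95. YAP/TAZ targets had medians of 0.24 in A549, -0.06 in H1299 and -0.32 in the pair labelled H2030, so A549 differed from H1299 by 0.30 and from the pair labelled H2030 by 0.56. Mesenchymal and EMT genes had medians of 0.17 in A549 and -0.25 in the pair labelled H2030, a gap of 0.42. G2/M-phase genes had medians of 0.31 in the pair labelled H2030 and -0.04 in H1299, a gap of 0.34. DUSP1 was at 41 and 64.8 FPKM with empty vector and malin in A549 and at 83.4 and 23.3 FPKM in the libraries labelled H2030.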

How the results depend on the processing

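The comparison of A549 with H1299 alone was chosen after the data were seen. The mean log2 difference of NHLRC1 stayed positive under all alternatives run, from 1.89 with a pseudocount of 5 to 3.83 with 0.1, and the lines left out in turn gave 1.91 to 3.48. The count of genes past the threshold in limma stayed at 0, except that leaving out each line gave 0 to 1. Without the replicate block it was 0, with 0 genes at an unadjusted p under 0.05. That fit called 7 lists with the preset correlation, but of the 6 lists the S-phase call was lost (limma camera, adjusted p = 0.211). The number of lists called, 6 in the main fit, was 0 with an estimated correlation and 0 by fry, and 4 to 9 when each line was left out. The 4 were called without the libraries labelled H2030, and none of the 6 was among them. Leaving out each line gave mean log2 differences of -0.48 to -0.0092 for histones and -0.0056 to 0.19 for glycolysis, and without the libraries labelled H2030 camera placed both on the opposite side. Counts of genes at 2-fold moved with the pseudocount, by construction, since it shrinks low genes: with 0.1 they were 153 in A549, 120 in H1299 and 546 in the pair labelled H2030, and with 5 they were 4, 3 and 65. With a mean FPKM of at least 5 they were 5, 5 and 144, and without a filter H1299 had 17. At 1.5-fold they were 134, 58 and 1413. Genes shared by all 3 lines at 1.5-fold became 3 higher and 2 lower with a pseudocount of 0.1, and 4 higher and 2 lower without the libraries labelled H2030, where fewer lines must share them. Of 513 log2 differences between vectors of named genes under the alternatives 511 kept their direction and 65 moved by over 1.5 times. The exceptions were GYS1 in H1299 with median-of-ratios scaling (-0.0048) and quantile normalization (-0.0065). Within a line the pseudocounts and filters cannot turn a direction, so they do not test it. Leaving out a line or the block cannot turn the mean of genes with the same direction in all 3 lines. Median-of-ratios scaling and quantile normalization were the alternatives that could. Depth limits the ratio of NHLRC1 in the pair labelled H2030, whose empty-vector value rests on an estimated 3 fragments. Restriction to genes whose FPKM confidence intervals do not overlap was not run, because no intervals were used here.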

Other observations

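The camera tests over lines and the matched random lists within a line were chosen before the data were examined. The tests of the ATF4 list's level per library and of the 21 identity genes were chosen before their results but after related genes had been seen, and the other tests in this part after their results had been seen.

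In the pair labelled H2030, the 22 genes of the unfolded protein response had a median log2 difference of -0.08, within the range of matched random lists (12.2nd percentile), with XBP1 at 174.1 against 60.3 FPKM and DNAJB9 at 12.5 against 4.3 FPKM. The 29 p53 targets had a median of 0.02 (76.5th percentile), with 15 higher and 14 lower, GADD45A among the latter at 78.4 against 24.3 FPKM and CDKN1A at 19.3 against 8.93 FPKM. The 30 G2/M-phase genes had a median of 0.31 (100th percentile), with CCNB1 at 52.6 against 102.2 FPKM, and the 30 S-phase and E2F targets -0.13 (2.41st percentile), with CDT1 at 62.9 against 36.6 FPKM. The G2/M-phase list did not pass over lines (limma camera, adjusted p = 0.0855). The 31 proteasome genes had a median of 0.08, at the 53.4th percentile of matched random lists, although 22 of them were higher, and the list passed no test over lines (limma camera, adjusted p = 0.182).

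The column of the empty-vector library labelled H2030 is headed H2030. That of the malin library is headed with the short name of HEK293T, a human embryonic kidney line. A different line in that library alone is argued against by the correlation of 0.975 with its empty-vector partner, against 0.758 to 0.818 between lines, and carry-over from A549 or H1299 by genes specific to those lines, whose median level was at most 0.148% of the source. Whether both libraries may come from another line such as HEK293T stays open: the 21 carcinoma genes had a median of -1.22 relative to the lower of the other lines, between the bounds set beforehand, NEFL and NEFM were higher than in both other lines, and NEFH and INA were not. No biological explanation was tested.

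More genes differed by 2-fold in the pair labelled H2030 than in the others. Counting noise as the only source is argued against, since 108 genes did so among those with a mean FPKM of at least 10, against 4 in A549 and 2 in H1299. That mean was over the 6 libraries, so some of the 108 were low in the pair itself, GDF15 among them (2.05 against 0.18 FPKM). Others were not, such as ASNS (341.7 against 106.2 FPKM). How many were low there was not counted. Whether the NHLRC1 level sets the number stays open, since the lines had 1 pair each. H1299, with the highest level, had 10 such genes, against 14 in A549 and 254 in the pair labelled H2030. The ATF4 list had a median log2 level in the empty-vector library labelled H2030 that was 1.25 above the highest of the other 5 libraries. Its malin partner, at 4.11, lay within the 3.34 to 4.71 of the other 4. A candidate explanation for these genes alone in that pair is a stressed state of that empty-vector culture. It leaves out A549, where the list was also lower with malin (median log2 difference -0.10, 0.01st percentile of matched random lists). In H1299 the list was at the 8.13th percentile. The explanation also leaves out HSPA1A, whose malin library stood apart, at 1006 FPKM against 99.2 to 161.4 in the other 5. Of the 254 genes at 2-fold, the empty-vector library alone lay outside the A549 and H1299 range in 62, the malin library alone in 47 and both in 123. An effect of malin stays open and untested, with 1 library per vector.

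SULT1A3, SULT1A4 and readthrough genes were among the largest differences within lines. For SULT1A3 with SULT1A4 and BOLA2 with BOLA2B there were 4 cases in which a gene differed by over 1 on the log2 scale, enough to move the summed FPKM of both by at least 0.37 on its own, and the sums differed by a median of 0.0955 and at most 0.17. A candidate explanation for these copies is fragments assigned to different copies in different libraries. For the readthrough genes this stays open, since in their 4 cases the gene alone would have moved the sum by at most 0.21, too little for the sum to decide. A malin effect on the choice between copies was not tested.

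There are 4 splits of the libraries that part every pair, the others differing from the real one by exchanging the vectors within 1 line, and with 4 splits no share under 0.05 can be reached. The real split gave 0 genes past the limma threshold and the highest other also 0, a count that cannot tell the splits apart. In the real split 213 genes (1.75%) had an unadjusted p under 0.05 (limma), fewer than the share of 0.05 expected with no differences. For lists the real split called 6 with the preset correlation and the others 8, 10 and 13.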
